A study of Mus musculus with 10 samples.

How the data were processed

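Expression of messenger RNA was measured in 10 samples of mouse T helper cells, with 1 array for each sample. The cells were CD4-positive lymphocytes from spleens of female BALB/c mice aged 10 to 14 weeks, cultured as Th0 (3 samples), Th2 (3 samples) or Th17 cells (4 samples). Groups and replicate numbers were taken from the sample titles. The description of the sample titled Th2 replicate 3 carries the number 4, and the title's number is used here. The titles call the replicates biological, but no source used here says whether they came from separate animals, so the p-values measure the spread between these samples.

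Per the labels' protocols, RNA was isolated with a column kit that keeps small RNA and treated with DNase. It was then amplified with a whole-transcriptome kit for small amounts of RNA and labelled with biotin. Per the submitters' processing notes, the authors deposited log2 values made by RMA (robust multi-array average: background correction, quantile normalization and a summary per probe set) in Affymetrix Expression Console 1.3.0.187. Quantile normalization is meant to give every array the same distribution, so a change in total RNA per cell cannot be seen in these values. The deposited values still differed in distribution. Their interquartile range ran from 1.95 on Th2 replicate 3 to 2.41 on Th2 replicate 1, and their median from 3.61 to 3.39 on the same arrays. RMA also compresses differences between weakly expressed genes, so their fold changes are understated. The genome build and the version of the probe set annotation are not given in the sources used here, and no coordinates are printed.

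The table held 41345 probe sets with values from 1.49 to 13.8. A probe table paired 23521 probe sets with 1 gene symbol and 1814 with several, and 16010 probe sets were not in it. Symbols were compared through Entrez IDs with the RefSeq gene table of assembly GRCm38.p6. Of the IDs 23328 matched and 0 symbols changed. Probe sets with exactly 1 symbol were used. Where a gene had several, as 1082 genes did, the probe set with the highest mean over the 10 arrays stood for it, which left 22180 genes. Genes without such a probe set were not analysed here, and some genes are not reported here. No filter on low values was used.

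Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 3 group means was fitted to all 10 arrays with lmFit, which left 7 residual degrees of freedom, and its variances were moderated with eBayes. The 3 contrasts were Th2 minus Th0, Th17 minus Th0 and Th17 minus Th2. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a contrast, and a gene was called at an adjusted p under 0.05. Fold changes are differences of mean log2 values, and folds are given on the linear scale with the direction in words. The error of a group mean is the SD over its arrays and that of a difference is the SE of the moderated fit. The number of arrays limits the precision.

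26 gene lists were tested with limma's camera at its preset correlation of 0.01 between genes. They covered the Th2, Th17 and Th1 programmes and interferon-induced, Treg-associated, TGF-beta response, IL-6 and STAT3 response and Tfh-associated genes. They also covered naive and resting T cell genes, T cell activation genes, cell cycle genes, glycolysis and hypoxia genes and cholesterol biosynthesis genes. Further lists held unfolded protein and amino acid stress genes, heat shock and immediate early genes, p53 and apoptosis genes, cytotoxic genes, chemokines and chemokine receptors, aryl hydrocarbon receptor genes and microRNA pathway genes. The other lists were T cell identity genes and markers of B cells, myeloid cells, CD8 and NK cells, basophils and mast cells, and erythroid cells and platelets. Some genes stand in several lists. The 78 tests (26 lists in 3 contrasts) were adjusted together. Each was repeated with a correlation estimated from the residuals, and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Adjusted p-values of lists are camera's with the preset correlation unless another test is named.

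Genes named in the text follow a rule. Per contrast these are the 10 called genes with the largest increase and the 10 with the largest decrease whose groups do not overlap. This leaves out unnamed gene models, small RNA genes, antigen receptor segments and olfactory and vomeronasal receptors. Gata3, Il4, Il5, Il13, Il17a, Il17f, Il23r, Tbx21, Ifng and Foxp3 are named whatever the test gives. Up to 4 members stand for a list: the called ones with the largest change, or up to 2 with the smallest p where no member was called. For lists that did not pass, not all of these are printed. Other genes named were chosen after their values were seen. The groups, contrasts, lists, naming rule and the alternatives not marked as added were set before the data were examined.

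The procedure was tested on simulated data with the real genes' means and moderated SDs, in which 200 of the 22180 genes were changed. For Th17 against Th0 it recovered 59.8% of the genes changed by 1 on the log2 scale and 97.3% of those changed by 2. The shares were 59.0% and 96.7% for Th17 against Th2 and 49.0% and 96.1% for Th2 against Th0. Of the calls 4.67%, 4.65% and 5.66% were false, in the same order. The simulated arrays varied independently from gene to gene, unlike the real ones.

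Alternatives were the replicate number as a block (from the title or the description), centring each array on its median, quantile normalization of the genes, a variance trend with robust moderation, and array weights. Others were fits of only the groups compared, the mean of a gene's probe sets, all probe sets, filters at the median or the 25th percentile on 3 arrays, and leaving out each array in turn. 3 alternatives were added after seeing the data: leaving out the 3 arrays apart on the first principal component, leaving out the 3 arrays highest in basophil and mast cell markers, and the interquartile range of each array's values as a covariate. Other splits of the arrays into groups of the same sizes were counted, 10 for Th2 against Th0 and 35 for each comparison with Th17. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.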

Results

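The 10 arrays compared 3 populations of T helper cells, the CD4-positive lymphocytes that direct other immune cells through the cytokines they release. All cultures received antibodies against CD3 (4 µg/ml) and CD28 (30 ng/ml), which stimulate the T cell receptor and its costimulatory receptor. Th2 cultures (n = 3) also received IL-4 at 100 ng/ml. Th17 cultures (n = 4) received IL-6 at 20 ng/ml, TGF-beta at 5 ng/ml and IL-23 at 10 ng/ml. Both of these groups, but not the Th0 control (n = 3), received an antibody against interferon gamma at 10 µg/ml, so each comparison with Th0 also sets cultures with that antibody against cultures without it. The medium was exchanged at 72 h. The time of harvest is not given in the sources used here.

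Arrays of a group were not alike. The first principal component held 35.8% of the variance and did not follow the groups: Th2 replicate 2 lay at 38.9, Th2 replicate 3 at 55.8 and Th17 replicate 4 at 37.5, and the remaining arrays at -0.96 or below. Cell cycle genes had a mean log2 expression of 6.09, 6.12 and 6.42 on those 3 arrays, against 7.59 on Th2 replicate 1, but Th17 replicate 2, which did not stand apart, was also low at 6.29. T cell activation genes had means of 8.96 and 8.64 on Th2 replicates 2 and 3, against 7.69 on Th2 replicate 1 and 8.13 on Th17 replicate 4. Markers of basophils and mast cells, cells that also make IL-4, had means of 6.50 on Th0 replicate 1 and 5.43 and 5.42 on Th17 replicates 2 and 3, and 4.18 or less on each other array. Cpa3, a mast cell and basophil protease, was at 10.74, 9.28 and 9.35 there and at 6.86 or less elsewhere. S100a8, an abundant neutrophil transcript, was at 7.16 on Th17 replicate 1 and at 3.74 or less on the others. Ighm, the B cell immunoglobulin heavy chain, was highest on Th17 replicate 1 (10.41) and Th0 replicate 2 (9.68).

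**Figure D1:**
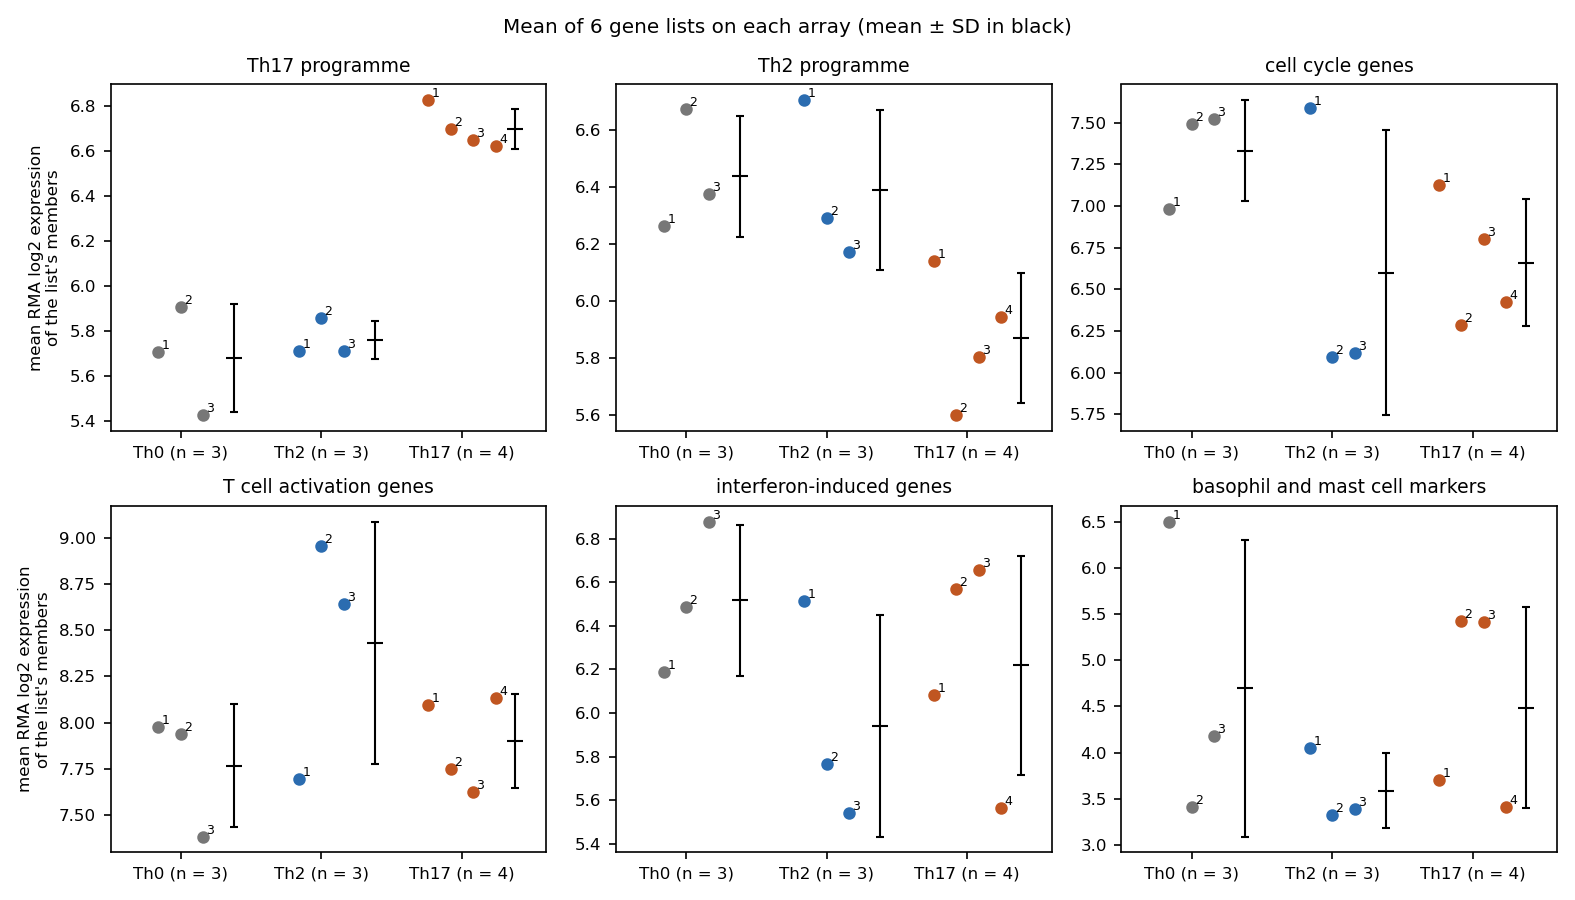
Mean RMA log2 expression of 6 gene lists on each of the 10 arrays (points, numbered by replicate), with group mean and SD in black. The Th17 programme lies between 6.62 and 6.83 on the 4 Th17 arrays and at 5.91 or less on the others, whereas cell cycle and T cell activation genes part Th2 replicate 1 from replicates 2 and 3 and basophil markers part arrays within the Th0 and Th17 groups.

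The comparison of Th17 with Th0 cells asks which transcripts differ after culture with IL-6, TGF-beta, IL-23 and the antibody against interferon gamma. Il17f (probe set 17221627), one of the signature cytokines of Th17 cells, rose most, from 5.41 ± 0.38 (SD, n = 3) in Th0 to 10.26 ± 0.57 (SD, n = 4) in Th17 cells, a difference of 4.85 ± 0.35 (SE) or 28.7-fold (limma, adjusted p = 0.000676). Il1r1, a receptor for interleukin 1, rose by 2.99 (7.94-fold), Ahr, the aryl hydrocarbon receptor, by 2.45 (5.45-fold) and Il23r, a chain of the IL-23 receptor, by 1.78 (3.45-fold). Gata3 (probe set 17381533), the transcription factor that directs the Th2 fate, fell by 1.92, from 7.75 ± 0.36 to 5.83 ± 0.36 (adjusted p = 0.0381). Gatm (probe set 17390810), an enzyme of creatine synthesis, rose 13.6-fold, from 3.45 ± 0.19 to 7.22 ± 0.79 (adjusted p = 0.00412).

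Among the other genes that rose, Cpd (carboxypeptidase D) rose 6.82-fold, Jun (a subunit of the AP-1 transcription factor) 5.88-fold, Pdpn (the membrane glycoprotein podoplanin) 5.71-fold, Klrd1 (the killer cell receptor chain CD94) 4.89-fold, Gpr15 (a homing receptor) 4.71-fold and Upp1 (uridine phosphorylase) 4.32-fold. S100a1, a calcium-binding protein, fell by 1.33. In Th2 against Th0, where no gene was called, Cpd differed by 1.23, Jun by 0.99, Upp1 by 0.29, Pdpn by 0.11, Klrd1 by -0.31 and Gpr15 by -0.50. Il17a, the other signature cytokine, was at 10.33 ± 0.17 in Th17 cells and at 7.55, 7.31 and 3.46 on the Th0 arrays. Its difference of 4.22 did not pass the test (adjusted p = 0.180). Of the cytokines and regulators of other T helper fates, Il4 differed by -1.10 (adjusted p = 0.852), Il5 by -0.01 (0.999), Il13 by -0.16 (0.999), Tbx21 by -0.52 (0.924), Ifng by 1.61 (0.906) and Foxp3 by -0.83 (0.971), none past the threshold.

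In total 23 genes changed, 21 higher and 2 lower, each by over 2-fold and with no overlap between the groups. Of all genes 7.57% did not overlap, where chance gives 5.71%. An unadjusted p under 0.05 was reached by 1146 genes, and 1109 are expected by chance. Il17f and Cpd were called without each of the 10 arrays in turn, and Gatm without 9 of them (3.67 with adjusted p = 0.0591 without Th0 replicate 3). The other calls were less stable. Gata3 stayed called only without Th2 replicate 1, and its adjusted p reached 0.174 without Th0 replicate 2, and Il1r1, Ahr, Il23r and Jun stayed called without 2 of the 10. Their differences kept their direction, from -2.08 to -1.72 for Gata3, 2.63 to 3.45 for Il1r1, 2.10 to 2.71 for Ahr, 1.56 to 2.03 for Il23r and 2.47 to 2.69 for Jun. The count moved with every array: it was 6, 8 and 2 without Th0 replicates 1, 2 and 3, 36, 5 and 4 without Th2 replicates 1, 2 and 3, and 9, 9, 6 and 12 without Th17 replicates 1 to 4. Leaving out a Th2 array cannot change a difference of Th17 from Th0 (that of Gata3 stayed at -1.92). It changes only the spread estimated over all groups and its degrees of freedom.

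**Figure D2:**
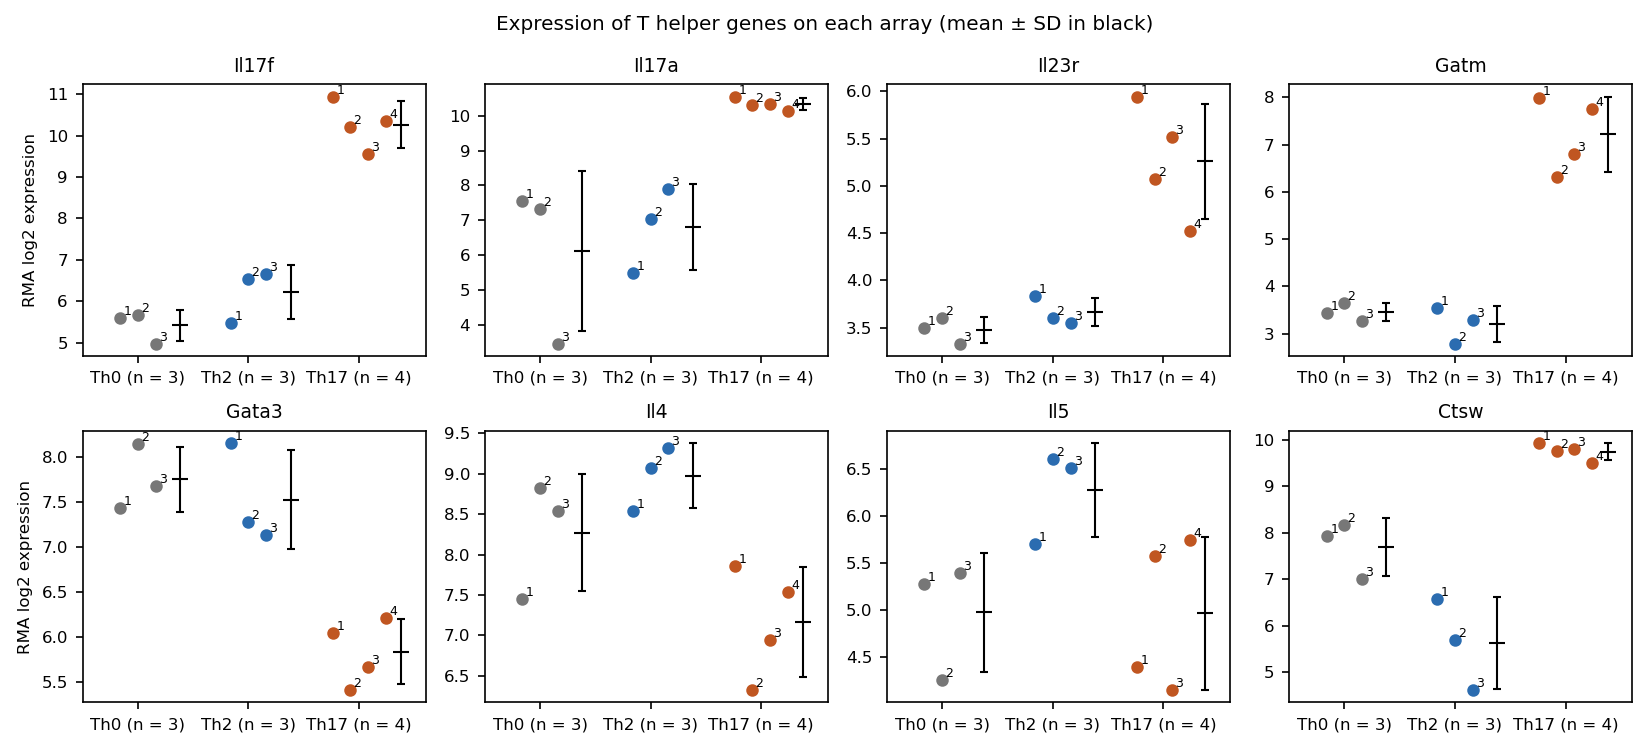
RMA log2 expression of 8 genes on each array (points, numbered by replicate) by group, with group mean and SD in black. All 4 Th17 arrays lie above every other array for Il17f, Il17a, Il23r, Gatm and Ctsw and below every other array for Gata3; Il17a spans 3.46 to 7.55 on the Th0 arrays.

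The Th17 programme rose as a list (adjusted p = 2.17e-14, and adjusted p = 0.0126 with an estimated correlation). Of its 29 measured members 22 had higher values in Th17 cells. Il17f, Il1r1, Ahr and Il23r rose, and 13 members were higher and none lower when adjusted over the list alone. Its mean lay between 6.62 and 6.83 on the Th17 arrays and between 5.42 and 5.91 on the Th0 arrays, and no single array ended the call. The Th2 programme fell (adjusted p = 9.6e-06, and adjusted p = 0.0646 with an estimated correlation), with 23 of 26 members lower. Gata3 was the 1 member called, and 6 were lower adjusted over the list alone.

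IL-6 and STAT3 response genes rose by a median of 0.37 (adjusted p = 1.82e-06, and adjusted p = 0.0959 with an estimated correlation), with Il23r called and 4 of 19 members higher adjusted over the list alone. TGF-beta response genes rose by a median of 0.38 (adjusted p = 4.03e-05, and adjusted p = 0.0646 with an estimated correlation). Pmepa1, a feedback inhibitor of TGF-beta signalling, rose 2.21-fold and 6 of 19 members were higher adjusted over the list alone. Aryl hydrocarbon receptor genes rose (adjusted p = 0.000771, and adjusted p = 0.0646 with an estimated correlation), with Ahr called over all genes and 3 of 10 members higher adjusted over the list alone. Naive and resting T cell genes rose (adjusted p = 4.15e-05, and adjusted p = 0.385 with an estimated correlation). 0 of 22 members were called over all genes by limma and 7 were higher adjusted over the list alone, with Itgae, the integrin CD103, at 2.08 (adjusted p = 0.0804) and Foxo1 at 0.79 (adjusted p = 0.0838). The means of that list were 6.91, 7.18 and 7.02 on Th17 replicates 1 to 3 and 6.13, 6.56 and 6.31 on the Th0 arrays, and Th17 replicate 4 lay below all Th0 arrays. Its call was lost without the 3 arrays highest in basophil and mast cell markers (adjusted p = 0.241).

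Cell cycle genes fell by a median of 0.67 (adjusted p = 2.29e-13, and adjusted p = 0.412 with an estimated correlation). Of 38 members 37 were lower and none was called over all genes or over the list alone. Kif11, a mitotic motor, differed by -1.11 (adjusted p = 0.879) and Cenpe, a kinetochore motor, by -1.18 (adjusted p = 0.879). The list's means were 7.13, 6.29, 6.80 and 6.42 on Th17 replicates 1 to 4 and 6.98, 7.49 and 7.52 on the Th0 arrays. Interferon-induced genes fell by a median of 0.24 (adjusted p = 0.00672, and adjusted p = 0.592 with an estimated correlation), with Cxcl10 at -0.54 (adjusted p = 0.879) and Psmb9 at -0.63 (adjusted p = 0.971). Their means were 6.08, 6.57, 6.66 and 5.57 on Th17 replicates 1 to 4, so the lowest was on the Th17 array that stood apart on the first component. That call ended without Th0 replicate 3 (adjusted p = 0.614) or Th17 replicate 4 (0.556).

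Chemokines and chemokine receptors rose (adjusted p = 0.00195, and adjusted p = 0.0829 with an estimated correlation), with Cxcr6 at 1.32 (adjusted p = 0.117) and Ccr7 at 0.91 (0.372), and Tfh-associated genes rose (adjusted p = 0.00787, and adjusted p = 0.0959 with an estimated correlation), with Il21 at 3.00 (adjusted p = 0.236) and Cd200 at 0.96 (0.945). Both calls ended without Th0 replicate 3 (adjusted p = 0.0676 and 0.0637). The Th1 programme rose (adjusted p = 0.0251, and adjusted p = 0.512 with an estimated correlation), with Il18r1 at 1.34 (adjusted p = 0.612) and Ccl5 at 1.36 (0.656). This call was lost without Th0 replicate 3 (0.536), Th2 replicate 2 (0.0519), Th17 replicate 2 (0.159) or Th17 replicate 3 (0.0758). Heat shock and immediate early genes rose (adjusted p = 0.0249, and adjusted p = 0.585 with an estimated correlation), with Jun called. That call ended without Th0 replicate 1 (0.0558), Th0 replicate 2 (0.0914), Th17 replicate 1 (0.170) or Th17 replicate 4 (0.0617). CD8 and NK cell markers rose (adjusted p = 0.0406, and adjusted p = 0.216 with an estimated correlation), with Klrd1 as the 1 member called. They lost the call without Th0 replicates 1 or 3, Th2 replicate 1, or Th17 replicates 1, 3 or 4 (adjusted p from 0.0518 to 0.213).

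Cholesterol biosynthesis genes fell (adjusted p = 0.0159, and adjusted p = 0.592 with an estimated correlation), with Lss at -0.65 (adjusted p = 0.879) and Sc5d at 0.89 (0.471). That call ended without Th0 replicate 2 (adjusted p = 0.967), Th17 replicate 2 (0.0776) or Th17 replicate 4 (0.140). Glycolysis and hypoxia genes fell (adjusted p = 0.0314, and adjusted p = 0.693 with an estimated correlation), with the glucose transporter Slc2a3 at -1.69 (adjusted p = 0.471) and Egln3 at 1.05 (0.928). Without Th0 replicate 2 their direction turned (adjusted p = 0.198), and without Th17 replicates 2 or 4 the call ended (0.214 and 0.256). B cell markers fell (adjusted p = 0.0469, and adjusted p = 0.467 with an estimated correlation), with H2-Ab1 at -0.61 and Cr2 at -0.27 (adjusted p = 0.999 each), and the call ended without Th0 replicates 1 or 2, Th2 replicates 1 or 2, or Th17 replicates 2, 3 or 4 (adjusted p from 0.0555 to 0.431). Basophil and mast cell markers did not pass (median difference -0.18, adjusted p = 0.617), with arrays high in them in both groups. Cytotoxic genes (adjusted p = 0.0539), T cell identity genes (0.0539), Treg-associated genes (0.984), T cell activation genes (0.771) and p53 and apoptosis genes (0.771) did not pass either (T cell identity genes were lower at 0.00190 without the 3 arrays highest in basophil markers), although Klrd1 of the cytotoxic and Nt5e (CD73, 3.97-fold) of the Treg-associated genes rose.

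In all, 16 lists passed in Th17 against Th0 with the preset correlation, 1 with an estimated correlation (the Th17 programme) and 4 with fry, and 10 passed without Th17 replicate 4. Those past fry were the Th17 programme (fry, adjusted p = 0.00420), TGF-beta response genes (0.0201), aryl hydrocarbon receptor genes (0.0201) and the Th2 programme (0.0469). Leaving out the 3 arrays highest in basophil and mast cell markers left 3 called genes, Il17f, Gatm and Pdpn. That setting compared Th17 replicates 1 and 4 with Th0 replicates 2 and 3, so having fewer arrays could by itself lower the count. Cpd was not called there (limma, adjusted p = 0.154), though its difference lay between 2.57 and 2.98 in all 23 settings. Leaving out the 3 arrays apart on the first component gave 46 genes, of which 14 were among the 23 called with all arrays. Without the 3 arrays apart the calls of interferon-induced genes (adjusted p = 0.485), glycolysis and hypoxia genes (0.325), cholesterol biosynthesis genes (0.0896), B cell markers (0.234) and CD8 and NK cell markers (0.0620) were lost. Without the 3 arrays highest in basophil and mast cell markers those of the Th1 programme (adjusted p = 0.408), Tfh-associated genes (0.0696), B cell markers (0.378) and CD8 and NK cell markers (0.0856) were lost.

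The comparison of Th17 with Th2 cells sets the 2 polarised populations against each other, both cultured with the antibody against interferon gamma. Ctsw (probe set 17361605), cathepsin W, a protease of cytotoxic lymphocytes, rose most: it was at 9.74 ± 0.18 (SD, n = 4) in Th17 and 5.63 ± 0.98 (SD, n = 3) in Th2 cells, a difference of 4.11 ± 0.40 (SE) or 17.3-fold (limma, adjusted p = 0.00446). Il17f was 16.4-fold higher and Gatm 16.2-fold higher in Th17 cells (adjusted p = 0.00321 each). Gpr15 rose 6.65-fold, Klrd1 6.07-fold, Pdpn 5.28-fold, Itgae 5.15-fold, the protease Adam19 5.15-fold, the collagen-modifying enzyme Plod2 4.06-fold and Nt5e 3.97-fold. Clec2i fell by 1.72, Gramd1b by 1.66, the MAP kinase phosphatase Dusp6 by 1.64 and S100a1 by 1.39.

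Of the cytokines and regulators named in each comparison only Il17f passed here. Gata3 differed by -1.69 ± 0.28 (SE, adjusted p = 0.0769), Il4 by -1.81 (0.241), Il5 by -1.31 (0.616) and Il13 by -0.43 (0.945), whereas Il17a differed by 3.53 (adjusted p = 0.328) and Il23r by 1.60 (0.0866). Gata3 and Il4 were lower on each of the 4 Th17 arrays than on each of the 3 Th2 arrays. Tbx21 differed by -0.08 (adjusted p = 0.995), Ifng by 0.20 (0.996) and Foxp3 by 0.48 (0.937).

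In total 17 genes changed, 13 higher and 4 lower in Th17 cells, each by over 2-fold and with no overlap between the groups. Of all genes 5.60% did not overlap, where chance gives 5.71%. An unadjusted p under 0.05 was reached by 1386 genes, against 1109 expected. Ctsw, Gatm and Il17f were called without each of the 10 arrays in turn, and Plod2 without 9 (2.04 with adjusted p = 0.0725 without Th2 replicate 2). Gramd1b and Nt5e stayed called without only 1 of the 10, and Clec2i without 2. Itgae and Dusp6 also stayed called without 2 of the 10, with Dusp6 at adjusted p from 0.0510 to 0.230 without another. Their differences ran from 2.14 to 2.59 and from -1.83 to -1.48. The count was 298 without Th2 replicate 1, 3 without Th2 replicate 2, 9 without Th2 replicate 3, 11 without Th0 replicate 2, and 8, 8 and 10 without Th17 replicates 1, 2 and 3. Without the 3 arrays highest in basophil and mast cell markers it was 6: Adam19, Cldnd1, Gatm, Il17f, Pdpn and Plod2, and Ctsw was no longer called (adjusted p = 0.249), at a difference of 4.08 ± 0.57 (SE) that was about as large as with all arrays. Leaving out the 3 arrays apart on the first component keeps Th2 replicate 1 as the lone Th2 array, so the other groups supply the spread and each value given for this setting rests on that array. The count there was 16, 8 higher and 8 lower. Only 6 of the 17 stayed called there, Il17f and Ctsw among them, and Gatm was no longer called (adjusted p = 0.0877), at a difference of 3.50 ± 0.52 (SE) against 4.02 ± 0.36 with all arrays.

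The Th17 programme rose (adjusted p = 1.87e-12, and adjusted p = 0.0126 with an estimated correlation), with 21 of 29 members higher, Il17f called and 15 higher adjusted over the list alone. The Th2 programme fell (adjusted p = 1.62e-05, and adjusted p = 0.0646 with an estimated correlation); 22 of 26 members were lower, Dusp6 was called, and 3 members were lower and 1 higher adjusted over the list alone. IL-6 and STAT3 response genes rose by a median of 0.52 (adjusted p = 6.1e-09, and adjusted p = 0.0646 with an estimated correlation), with 0 of 19 called over all genes by limma and 8 higher adjusted over the list alone. Rora differed by 1.17 (adjusted p = 0.0586). TGF-beta response genes rose (adjusted p = 0.00272, and adjusted p = 0.0959 with an estimated correlation), with Itgae called and 3 higher and 1 lower adjusted over the list alone. The call was lost without Th2 replicate 3 (0.0531). Aryl hydrocarbon receptor genes rose (adjusted p = 0.000171, and adjusted p = 0.0646 with an estimated correlation), with 0 of 10 members called over all genes by limma and 4 higher adjusted over the list alone. Ahr differed by 2.37 (adjusted p = 0.0502) and Il22 by 2.04 (0.353). Naive and resting T cell genes rose (adjusted p = 4.29e-06, and adjusted p = 0.320 with an estimated correlation), with Itgae called and 7 higher and 1 lower adjusted over the list alone. The means of that list were 6.72, 6.01 and 5.47 on Th2 replicates 1 to 3 and 6.91, 7.18 and 7.02 on Th17 replicates 1 to 3, and Th17 replicate 4 lay below Th2 replicates 1 and 2. The adjusted p was 0.0128 without Th2 replicate 3 and 0.0223 without the 3 arrays apart.

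T cell activation genes fell by a median of 0.46 in Th17 against Th2 cells (adjusted p = 4.52e-06, and adjusted p = 0.320 with an estimated correlation). Of 25 members 21 were lower and 0 were called over all genes by limma, with 2 lower adjusted over the list alone: Egr1, an immediate early transcription factor, at -1.77 (adjusted p = 0.296) and Egr3 at -1.51 (0.337). Egr1 was at 6.41 on Th2 replicate 1 and at 8.60 and 7.94 on Th2 replicates 2 and 3. The mean of the activation genes was 7.69 on Th2 replicate 1, inside the 7.63 to 8.13 of the Th17 arrays, and 8.96 and 8.64 on Th2 replicates 2 and 3. That call was lost without the 3 arrays apart (adjusted p = 0.798). Heat shock and immediate early genes fell (adjusted p = 0.00109, and adjusted p = 0.467 with an estimated correlation), with Hspa1b at -2.01 (adjusted p = 0.672) and Jun at 1.56 (0.296), and the call ended without Th2 replicate 2 (0.134) or the 3 arrays highest in basophil markers (0.0717). Their direction turned without the 3 arrays apart (0.0636). p53 and apoptosis genes fell (adjusted p = 0.00117, and adjusted p = 0.0646 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at -0.69 (adjusted p = 0.383) and Tnfrsf10b at -0.89 (0.578).

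Glycolysis and hypoxia genes rose (adjusted p = 0.000181, and adjusted p = 0.538 with an estimated correlation), with Egln3 at 1.76 (adjusted p = 0.344) and Mxi1 at 1.55 (0.304). Their means were 7.15, 6.55, 6.88 and 6.54 on Th17 replicates 1 to 4 and 6.65, 6.33 and 6.26 on the Th2 arrays, and the call was lost without the 3 arrays apart (adjusted p = 0.170). Cytotoxic genes rose (adjusted p = 0.0159, and adjusted p = 0.512 with an estimated correlation), with Ctsw and Klrd1 called. Of 19 members 11 were higher and 8 lower, with a median of 0.11 against a mean of 0.43. That call ended without Th2 replicate 1 (0.453) or Th17 replicate 4 (0.123). CD8 and NK cell markers rose with Klrd1 called (adjusted p = 0.00542, and adjusted p = 0.0928 with an estimated correlation), chemokines and chemokine receptors rose as a list (adjusted p = 0.00816, and adjusted p = 0.116 with an estimated correlation), and the Th1 programme rose as a list (adjusted p = 0.00533, and adjusted p = 0.412 with an estimated correlation). Of their members Ccr7 differed by 1.34 (adjusted p = 0.0703), Ccl20 by 1.38 (0.606), Il18rap by 1.10 (0.143) and Il18r1 by 1.72 (0.267), none past the threshold. The 3 list calls ended without Th2 replicate 1 (adjusted p = 0.0706, 0.0507 and 0.214), and that of the Th1 programme also without the 3 arrays highest in basophil markers. Treg-associated genes rose (adjusted p = 0.0213, and adjusted p = 0.540 with an estimated correlation) with Itgae and Nt5e called, and the call ended without Th2 replicates 2 or 3 or Th17 replicates 1 or 4 (adjusted p from 0.0896 to 0.466). Against the lone Th2 array left without the 3 arrays apart the list was lower in Th17 cells (adjusted p = 0.0158). Interferon-induced genes rose (adjusted p = 0.00787, and adjusted p = 0.592 with an estimated correlation) with Gbp5 at 0.92 (adjusted p = 0.672) and Cd274 lower (0.606), and the call ended without Th2 replicates 2 or 3 or Th17 replicates 2 or 3 (adjusted p from 0.0868 to 0.385). The direction turned without the 3 arrays apart (0.573) and without the 3 arrays highest in basophil markers (0.0981).

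Basophil and mast cell markers rose by a median of 0.77 (adjusted p = 0.00452, and adjusted p = 0.540 with an estimated correlation), with Kit at 1.19 (adjusted p = 0.340) and Ms4a2 at 1.02 (0.911). They lost the call without Th17 replicate 2 (0.0613), 1 of the 2 Th17 arrays that were high in these markers. The adjusted p was 0.980 without the 3 arrays highest in them and 0.0597 without the 3 arrays apart. Cell cycle genes (adjusted p = 0.621), cholesterol biosynthesis genes (0.193), Tfh-associated genes (0.181), T cell identity genes (0.146) and B cell markers (0.476) did not pass. Against the lone Th2 array left without the 3 arrays apart, cell cycle genes (adjusted p = 1.92e-20) and cholesterol biosynthesis genes (0.00272) were lower in Th17 cells. In all 17 lists passed with the preset correlation, 1 with an estimated correlation (the Th17 programme) and 5 with fry. Those past fry were the Th17 programme (fry, adjusted p = 0.00420), aryl hydrocarbon receptor genes (0.0112), p53 and apoptosis genes (0.0364), CD8 and NK cell markers (0.0364) and IL-6 and STAT3 response genes (0.0470).

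**Figure D3:**
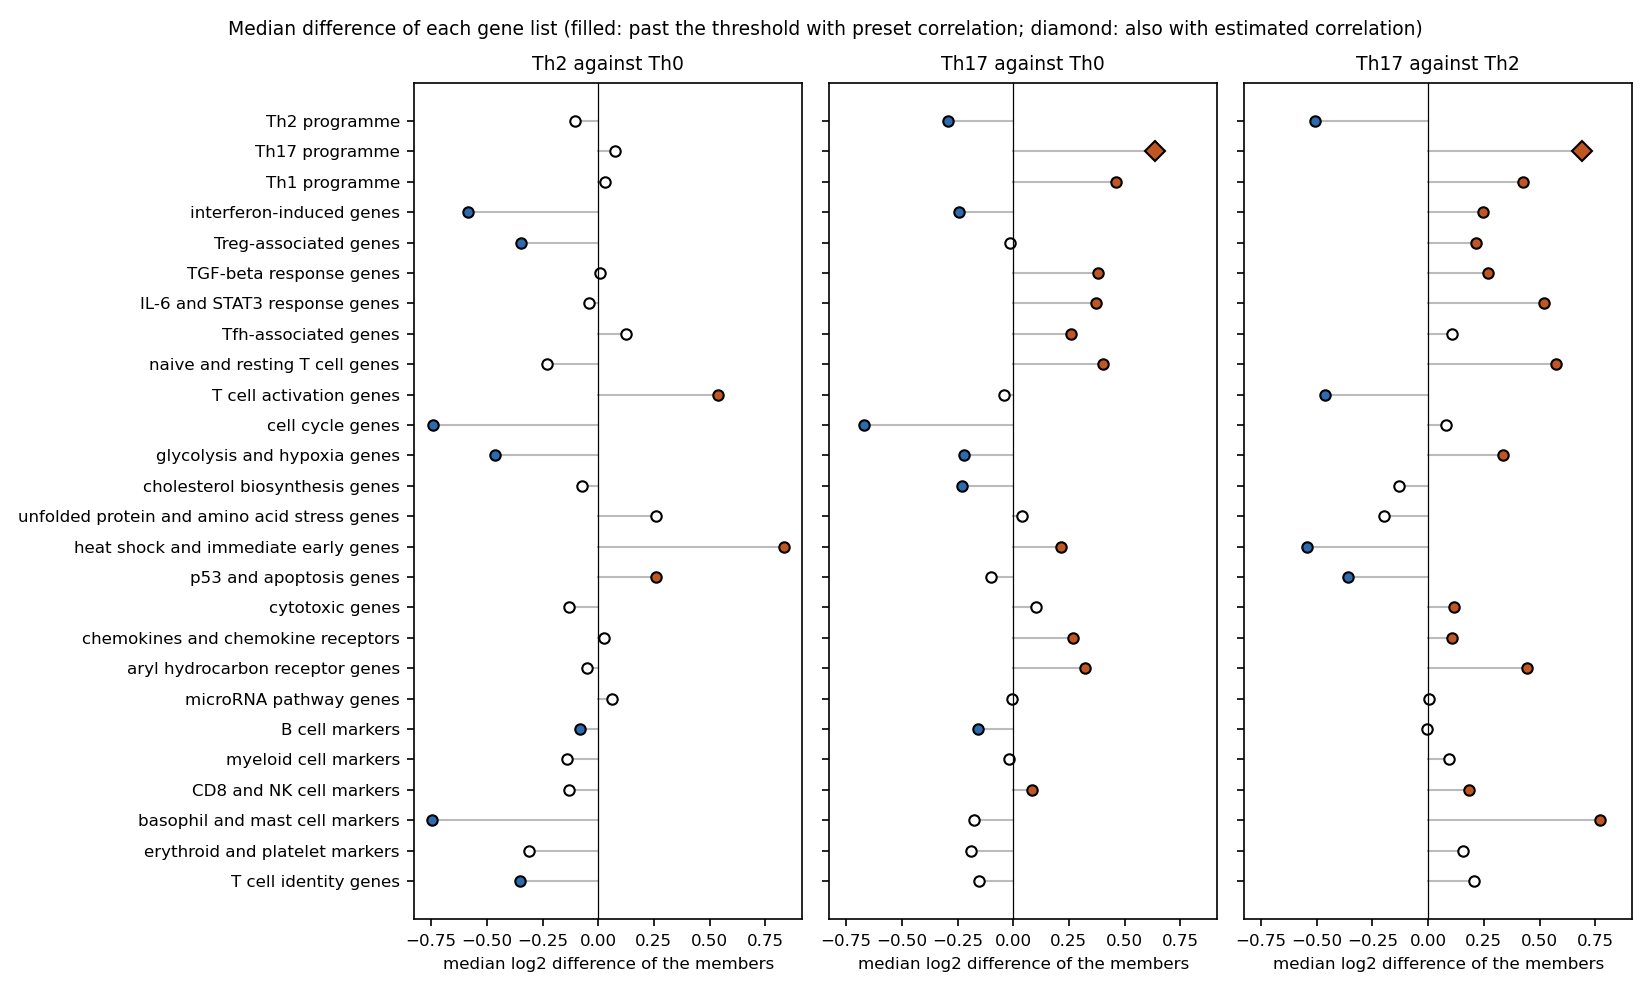
Median log2 difference of the measured members of each of the 26 gene lists in the 3 comparisons; filled points passed an adjusted p of 0.05 with camera's preset correlation (orange higher, blue lower), open points did not, and diamonds also passed with an estimated correlation. The Th17 programme has the only diamonds, at 0.64 against Th0 and 0.69 against Th2.

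The comparison of Th2 with Th0 cells asks which transcripts differ after culture with IL-4 and the antibody against interferon gamma. No single gene passed, and the genes that define Th2 cells did not separate as a group. Il4 (probe set 17262683) was at 8.98 ± 0.40 (SD, n = 3) in Th2 and 8.27 ± 0.72 (SD, n = 3) in Th0 cells, a difference of 0.71 ± 0.43 (SE, limma, adjusted p = 0.819). Il5 (probe set 17249586), another Th2 cytokine, was higher on each of the 3 Th2 arrays than on each Th0 array, at 6.27 ± 0.50 against 4.98 ± 0.63 (2.46-fold, adjusted p = 0.767). Gata3 differed by -0.23 (adjusted p = 0.927), Il13 by 0.27 (0.940), Ifng by 1.41 (0.795), Tbx21 by -0.43 (0.804), Foxp3 by -1.31 (0.767), Il17a by 0.70 (0.925), Il17f by 0.81 (0.793) and Il23r by 0.19 (0.943).

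At an adjusted p under 0.05 limma called 0 genes in Th2 against Th0, with 0.767 as the smallest adjusted p; 1407 genes had an unadjusted p under 0.05, where 1109 are expected, and 8.43% of genes did not overlap, where chance gives 10%. The count stayed at 0 with array weights, a variance trend, quantile normalization and the other planned settings on all arrays, and with the interquartile range as a covariate. It was 431 (177 higher and 254 lower) without Th2 replicate 1 and 1 (Car1, lower) without Th0 replicate 2. Without the 3 arrays apart on the first component, which leaves Th2 replicate 1 as the lone Th2 array and assumes that it varies like the other groups, 2 genes were called, Kcnma1 and Tanc2.

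As lists, cell cycle genes fell by a median of 0.74 in Th2 cells (adjusted p = 2.33e-12, and adjusted p = 0.420 with an estimated correlation). Of 38 members 37 were lower and 0 were called by limma, with Ccnb2 (cyclin B2) at -1.98 and Cenpf at -1.16 (adjusted p = 0.767 each). Their means were 7.59 on Th2 replicate 1, 6.09 and 6.12 on Th2 replicates 2 and 3, and 6.98, 7.49 and 7.52 on the Th0 arrays, and without the 3 arrays apart the list was higher in Th2 (adjusted p = 0.00232). T cell activation genes rose by a median of 0.54 (adjusted p = 7.73e-06, and adjusted p = 0.327 with an estimated correlation), with 2 members higher adjusted over the list alone, the cytokine Tnf at 1.65 and Egr1 at 1.69 (adjusted p = 0.767 each over all genes). Heat shock and immediate early genes rose by a median of 0.84 (adjusted p = 1.34e-07, and adjusted p = 0.237 with an estimated correlation), with all 13 members higher, 1 of them, Ier2 at 1.03, when adjusted over the list alone, and the chaperone Hspa1a at 1.45 (adjusted p = 0.767 over all genes). On Th2 replicates 1, 2 and 3 the means were 7.69, 8.96 and 8.64 for activation genes and 5.72, 7.39 and 6.81 for heat shock and immediate early genes. Without the 3 arrays apart both lists turned direction (adjusted p = 0.953 and 0.980).

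Interferon-induced genes fell by a median of 0.59 in Th2 cells (adjusted p = 1.35e-06, and adjusted p = 0.420 with an estimated correlation), with 36 of 41 members lower. Psmb10, an immunoproteasome subunit, differed by -1.68 and Cd274 by 0.98 (adjusted p = 0.767 each). Their means were 6.51, 5.77 and 5.54 on Th2 replicates 1 to 3 and 6.19, 6.49 and 6.88 on the Th0 arrays, and without the 3 arrays apart the direction turned (adjusted p = 0.953). Glycolysis and hypoxia genes fell by a median of 0.46 (adjusted p = 2.37e-08, and adjusted p = 0.385 with an estimated correlation), with all 24 members lower and Pfkp, a glycolytic enzyme, at -0.74 and the oxygen sensor Egln1 at -1.03 (adjusted p = 0.767 each). Their means were 6.65, 6.33 and 6.26 on Th2 replicates 1 to 3 and 6.56, 7.64 and 6.77 on the Th0 arrays, so Th2 replicate 1 lay above Th0 replicate 1 and the highest value was on Th0 replicate 2. The adjusted p was 0.0146 without Th0 replicate 2 and 0.0168 without the 3 arrays apart. T cell identity genes fell (adjusted p = 0.00214, and adjusted p = 0.512 with an estimated correlation). Of the members, Cd8a, a CD8 T cell marker that also stands in the CD8 and NK cell list, differed by -1.03 (adjusted p = 0.793) and Zap70 by 0.52 (0.807). The call was lost without Th0 replicate 2 (0.252) and the direction turned without the 3 arrays apart (0.720).

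p53 and apoptosis genes rose (adjusted p = 0.00336, and adjusted p = 0.0818 with an estimated correlation), with Trp53inp1 at 1.18 and Sesn2 at 0.97 (adjusted p = 0.767 each). That call ended without Th2 replicate 1 (0.0517). Treg-associated genes fell (adjusted p = 0.0314, and adjusted p = 0.559 with an estimated correlation) with Foxp3 at -1.31 and Cd83 2.83-fold higher (adjusted p = 0.767 each). That call ended without Th0 replicate 2 (adjusted p = 0.198), Th2 replicate 2 (0.214), Th2 replicate 3 (0.450) or Th17 replicate 4 (0.0606), and without the 3 arrays apart the list was higher (0.0197). Basophil and mast cell markers fell (adjusted p = 0.00118, and adjusted p = 0.526 with an estimated correlation), with all 10 members lower, Mcpt8 at -2.19 (adjusted p = 0.841) and Hdc at -0.81 (0.814) among them. They lost the call without Th0 replicate 1 (0.698), the array highest in them, without the 3 arrays highest in them (0.416) and without the 3 arrays apart (0.0929). B cell markers fell (adjusted p = 0.0159, and adjusted p = 0.385 with an estimated correlation), with H2-Ab1 at -1.12 and H2-Eb1 at -0.86 (adjusted p = 0.767 each), and the call ended without Th0 replicate 2 (0.175), Th2 replicate 1 (0.142) or Th2 replicate 2 (0.0519).

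The Th2 programme itself did not pass in Th2 against Th0 (median -0.11, 12 of 26 members higher, adjusted p = 0.990). Its means were 6.71, 6.29 and 6.17 on Th2 replicates 1 to 3 and 6.27, 6.68 and 6.38 on the Th0 arrays. The Th17 programme (adjusted p = 0.617), Th1 programme (0.617), TGF-beta response genes (0.269), IL-6 and STAT3 response genes (0.183), Tfh-associated genes (0.332), naive and resting T cell genes (0.562), cytotoxic genes (0.505), chemokines and chemokine receptors (0.840), aryl hydrocarbon receptor genes (0.700), cholesterol biosynthesis genes (0.498) and CD8 and NK cell markers (0.480) did not pass. Ctsw, a cytotoxic gene, differed by -2.07 (adjusted p = 0.767) and was the 1 member of its list past an adjustment over the list alone. With Th2 replicate 1 as the lone Th2 array, naive and resting T cell genes were higher (adjusted p = 0.000134) and cytotoxic genes lower (0.0122) in Th2. In all 10 lists passed with the preset correlation, 0 with an estimated correlation and 0 with fry, where 1 list had an unadjusted p under 0.05 in each.

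4 lists passed in no comparison. MicroRNA pathway genes had median differences of 0.06, -0.01 and 0.00 in Th2 against Th0, Th17 against Th0 and Th17 against Th2 (adjusted p = 0.592, 0.569 and 0.985), with Zc3h12a at 0.51 and Drosha at -0.48 in the first, Zc3h12a at 0.54 and Ago3 at 0.35 in the second and Ago2 at -0.30 and Ago1 at 0.26 in the third. Unfolded protein and amino acid stress genes had adjusted p of 0.146, 0.771 and 0.214, with Edem1 at -0.96 and Dnajb9 at 1.02 in the first, Dnajb9 at 0.70 and Herpud1 at 0.64 in the second and Psat1 at -0.61 and Trib3 at -0.58 in the third. Myeloid cell markers had adjusted p of 0.0940, 0.763 and 0.157, and erythroid and platelet markers, of which 5 were measured, 0.106, 0.134 and 0.750. With Th2 replicate 1 as the lone Th2 array, stress genes (adjusted p = 0.0298 higher in Th2 against Th0, 0.0201 lower in Th17 against Th2) and myeloid markers (0.0201 lower and 0.0354 higher) passed, and myeloid markers also without the 3 arrays highest in basophil markers in Th17 against Th2 (0.00976 higher). The median, mean and test of a list differed in sign only for lists that did not pass: the Th1 programme in Th2 against Th0, Treg-associated, T cell activation, microRNA pathway and myeloid lists in Th17 against Th0, and microRNA pathway genes and B cell markers in Th17 against Th2.

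The comparisons share arrays. 11 genes changed in both comparisons of Th17 cells, 10 higher (Il17f, Gatm, Pdpn, Klrd1 and Gpr15 among them) and S100a1 lower. Independent lists would share 0.0123 and 0.000361, and unchanged groups simulated with shared Th17 arrays shared 0 and 0. The first value leaves out the shared arrays and the second the effects, so the difference from either is not called a shared effect. With 2 Th17 arrays in each comparison, in 6 splits, 1 to 5 genes were called higher in both, and 0 lower. With 0 genes called in Th2 against Th0, none was called in both Th2 and Th17 against Th0. Across genes, which are not independent replicates, the log2 differences of Th2 and of Th17 from the same Th0 arrays correlated with r = 0.491, and unchanged groups simulated against shared controls gave 0.535. The covariance was 0.0473 against 0.0330 simulated, and 67.9% of genes had the same sign against 68.0% simulated. At an unadjusted p under 0.05, 105 genes were higher in both and 170 lower in both. Independent lists would share 18.6 and 17.6, and simulated unchanged groups 136 and 135. The 3 Th0 arrays are too few to be split, so part of any excess can come from them.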

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

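Among the 125 named genes and 26 list means, 8 had 1 Th17 array far from the other 3, measured as the gap to the nearest array against the range of the group. Chance marks about 1 in 20, or 7.55 of the 151, so their number gives no sign of anything beyond chance. Groups of 3 arrays were not tested in this way. Th17 replicate 1 had the lowest Tbx21, at 5.89 where the others lay between 6.26 and 6.33, and the lowest Nkg7, at 7.21 where the others lay between 8.06 and 8.17. The same array had the highest mean of myeloid cell markers, at 4.08 against 3.44 to 3.51. Th17 replicate 4 had the lowest Zap70 (7.08 against 7.89 to 7.97), Il18rap (4.11 against 4.66 to 4.68), Gbp5 (6.25 against 6.45 to 6.47) and mean of T cell identity genes (8.26 against 8.69 to 8.76), and the highest Tnfrsf10b (5.54 against 4.87 to 4.97).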

How the results depend on the processing

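Leaving out the arrays apart, leaving out the arrays highest in basophil markers and the interquartile range as a covariate were chosen after the data were seen. The cause was not tested for any change below, beyond fewer arrays or more probe sets in some settings. Genes called in Th17 against Th0, 23 in the report, were 7 with all probe sets, 60 with array weights, 6 with arrays centred on their medians, 85 with the interquartile range as a covariate, 46 without the arrays apart and 3 without the arrays highest in basophil markers, and 2 to 36 leaving out 1 array. Array weights and the covariate kept all 23 genes. The balance of directions moved too: 51 genes were higher and 34 lower with the covariate, and 10 higher and 6 lower with only the 2 groups fitted. In Th17 against Th2, 17 became 330 with array weights, 60 with the interquartile range, 30 with quantile normalization and 6 without the arrays highest in basophil markers, and 3 to 298 leaving out 1 array. In Th2 against Th0, 0 became 2 without the arrays apart and 0 to 431 leaving out 1 array, and genes called in both Th2 and Th17 against Th0 numbered 0 to 8. Lists past the threshold with an estimated correlation were 0, 1 and 1 (Th2 against Th0, Th17 against Th0, Th17 against Th2), with fry 0, 4 and 5, and the lists of Th17 against Th0 numbered 10 to 17 leaving out 1 array.

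Lists past the threshold in the report whose direction turned were, without the arrays apart, in Th2 against Th0 interferon-induced genes (adjusted p = 0.953), Treg-associated genes (0.0197), T cell activation genes (0.953), cell cycle genes (0.00232), heat shock and immediate early genes (0.980) and T cell identity genes (0.720), and in Th17 against Th2 interferon-induced genes (0.573), Treg-associated genes (0.0158) and heat shock and immediate early genes (0.0636). Interferon-induced genes in Th17 against Th2 also turned without the arrays highest in basophil markers (0.0981), and glycolysis and hypoxia genes in Th17 against Th0 without Th0 replicate 2 (0.198). Over the arrays left out that list's adjusted p ran from 5.47e-06 (without Th0 replicate 1) to 0.256 (without Th17 replicate 4). No named gene that was called changed direction, and Il17f was called in all 23 settings in both comparisons.

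The replicate numbers gave no pairing that held throughout: deviations from the group means correlated above 0.1 in 1 of 9 pairs by the title's number and 2 of 8 by the description's, and 1 and 3 arrays correlated best with their own number. The 2 arrays with the description's number 4, Th2 replicate 3 and Th17 replicate 4, had the highest r of these pairs (0.494), and both are among the arrays apart. What the number marks is not given in the sources used here. No Th0 array carries the number 4, so a difference it marked would enter only the Th2 and Th17 means of the main fit. With the title's number as a replicate block 8 genes were called in Th17 against Th0 and 11 in Th17 against Th2, and with the description's 5 and 5; either block left 10 lists in Th17 against Th0.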

Other observations

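The tests of weaker signal on Th2 replicates 2 and 3 and of basophils as the source of Il4 were chosen after the results were seen, as were the genes named in the next paragraph. The further early response and basophil genes were fixed after the patterns were seen and before their own values were looked at.

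Some transcripts stood out on single arrays. Kcnma1, a potassium channel, was at 6.88 on Th2 replicate 1 and between 2.70 and 2.93 on all other arrays, and Tanc2 was at 6.74 there and at 4.98 or less elsewhere. Car1, carbonic anhydrase 1, was at 5.39 and 4.66 on Th0 replicates 1 and 3 and at 3.00 or less elsewhere. The platelet chemokine Ppbp ranged from 3.35 on Th17 replicate 4 to 9.43 on Th0 replicate 1. Il2, the T cell growth factor, was at 5.24 on Th0 replicate 3 and 9.86 on Th0 replicate 1. Epas1, a Th2 programme member that encodes a hypoxia-inducible factor, was at 7.31, 8.18 and 6.12 on the Th0 arrays, 7.66, 4.94 and 4.44 on the Th2 arrays and 4.38 or less on the Th17 arrays (Th17 against Th0 adjusted p = 0.201).

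Th2 replicates 2 and 3 stood apart from replicate 1 in activation and cell cycle genes. The interquartile range of all values was 2.15 and 1.95 on these arrays and 2.41 on replicate 1. It was 2.08 on Th0 replicate 1, which did not stand apart on the first component. A weaker signal that follows mean expression alone did not account for these differences, though it may account for part of that in cell cycle genes. A difference in signal that follows other traits of the genes was not tested. On Th2 replicates 2 and 3 the median activation gene lay 1.25 and 1.09 above replicate 1. After each array's trend of difference against mean expression was removed, it lay 1.44 and 1.49 above, with 22 and 21 of 25 genes above replicate 1. The direction of this difference was known beforehand and removal widened it, so the test had little room to come out otherwise. The median cell cycle gene lay at -1.51 and -1.57 before removal and at -1.31 and -1.07 after it. A candidate explanation that stays open is more recent stimulation of these cells, since the harvest time is not stated: of 20 further early response genes, 10 had both arrays above the 8 others (exact binomial p = 4.43e-12 against a chance of 1 in 45, and 2.38e-08 against the 5.41% of all genes with that order). Nr4a2, Dusp2, Rel and Tnfsf14 were among the 10, and Tnfaip3, Nfkbia and Zfp36 were not; 1 of the 20 stands in another list or among the named genes. Genes are not independent, so these p-values are too small. Heat shock and immediate early genes, a list set as a sign of handling, also lay above replicate 1 after the trend was removed. Their medians were 1.74 and 1.10 above it, with 13 and 12 of 13 genes higher. Neither a difference in handling nor a true effect of IL-4 in 2 of 3 cultures was separated from more recent stimulation.

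Markers of basophils and mast cells were high on Th0 replicate 1 and Th17 replicates 2 and 3, although a CD4 isolation kit, which should remove such cells, had been used. Basophils among the cultured cells may account for this: of 18 further basophil genes measured, 7 (Slc18a2, Alox5ap, Alox5, Csf2rb, Csf2rb2, Cd63 and Lat2) had the same 3 arrays on top (exact binomial p = 8.19e-11 against a chance of 1 in 120, and 2.11e-10 against the 0.956% of all genes with that order), and 2 of the 18 stand in another list or among the named genes. Cpa3, Mcpt8 and Fcer1a, abundant in such cells, reached 10.74, 9.54 and 8.40 on Th0 replicate 1. Basophils as the main source of Il4 transcript were argued against, since Il4 was higher in 0 of the 3 arrays than in any array of its group outside the 3: it was at 7.45 on Th0 replicate 1 against 8.82 and 8.54, and at 6.33 and 6.94 on Th17 replicates 2 and 3 against 7.86 and 7.54. Whether growth of such cells in culture or incomplete isolation brought them was not tested.

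Over all genes Th2 replicate 1 lay close to Th17 replicates 1 to 3 (r from 0.969 to 0.975). Th17 replicate 4 lay further from the Th0 arrays (0.944 to 0.952). Th2 replicate 1 also lay close to the Th0 arrays (r from 0.961 to 0.981), and Th2 replicates 2 and 3 did not (0.937 to 0.951). Its r with Th0 replicates 2 and 3 was 0.981 each. That was above its r with every Th17 array and above the r of those Th0 arrays with each other (0.976). A mislabelled sample could give this: on 200 genes chosen to separate Th2 replicates 2 and 3 from Th0 arrays, on a scale with Th0 at 0 and those Th2 arrays at 1, Th2 replicate 1 lay at -0.026 (median of 3 choices of Th0 arrays, from -0.0848 to 0.0354), and Th0 arrays left out in turn lay at -0.058, 0.098 and 0.255. The result would be the same for a Th2 culture that did not share what set replicates 2 and 3 apart, so a Th0 sample under a Th2 label stays open and is not shown. On Th2 replicate 1 Il5 (5.70) was above and Tbx21 (5.79) and Ctsw (6.58) below all 3 Th0 arrays. These genes were chosen after their values were seen and decide nothing. No biological explanation was tested for this pattern.

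Other splits of the arrays bear on the counts in the report. In Th17 against Th0 the real split was the 1 of 35 with the most genes (23, and 13 for the highest other split) and the 1 with the most lists (16, and 14 for the highest other), so chance alone was argued against for both counts. The other splits gave 3 to 14 lists with the preset correlation. Many lists thus passed under other groupings too, and the count says nothing for any single list. In Th17 against Th2, 2 of 35 splits gave as many genes as the real 17, so chance cannot be excluded for that count; the highest other gave 1441 and set Th2 replicate 1 and Th17 replicates 1, 2 and 3 against Th2 replicates 2 and 3 and Th17 replicate 4, which points to a structure of the samples along the first component. For the lists of that comparison 1 of 35 splits gave as many as the real 17, with 15 as the highest other, so chance alone was argued against for that count. The other splits gave 3 to 15 lists, so here too the count says nothing for any single list. In Th2 against Th0 the 10 splits are too few for a share under 0.05: all 10 gave as many genes as the real 0, with 32 as the highest other, and 3 gave as many lists as the real 10, with 12 as the highest other.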
